A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

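The series holds 4 Affymetrix Rice Genome arrays, 2 of ZH11 and 2 of ila1 lamina joints at the tillering stage, grouped by the sample titles. The deposited values are 1 linear intensity per probe set and array for 57381 probe sets. Per the labels' protocols, RNA was extracted with TRIzol and biotinylated cRNA was prepared by the standard Affymetrix protocol. The software and the scaling that turned scans into intensities are not given in the sources used here. The values fit a linear scale, with a lowest value of 1 on each array and highest values from 13265 to 13980, but whether the arrays had been scaled to each other stays unknown. Scaling was therefore among the alternatives. Nothing in the sources says from how many plants each replicate came, so p-values measure the spread between these samples.

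The 123 probe sets marked as Affymetrix controls were left out, 16 was added to each intensity, and log2 was taken. Fold changes are on this scale and understate the change of low signals. The 40% of probe sets with the lowest mean over all 4 arrays were not tested, which left 34355. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the prior variance, two-sided, with genotype as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. With 2 residual degrees of freedom the fit drew on a prior worth 2.91 degrees of freedom. Probe sets at least 2-fold apart in all 4 pairs of an ila1 and a ZH11 array were counted as a description without a test. Files and plots were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

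Probe sets were named through the platform annotation given with the values. It pairs 22436 probe sets with exactly 1 gene and 95 with several, and 34850 are unnamed here. All 17905 genes were found in the RefSeq gene table of assembly ASM3414082v1, which was used for names only, so no coordinates are given. Of these genes, 2457 have a name beyond a locus or clone number. Where several probe sets read a gene, the gene lists used the one with the highest mean signal. The 64 probe sets for reporter and vector sequences are not marked as controls and were kept. Called probe sets of 1 gene went in both directions for 7 of the 262 genes with more than 1 called probe set.

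The design, the lists' subjects, the alternatives and the rule for named genes were chosen before the data were examined. Named genes are the 12 largest rises and 12 largest falls, by log2 fold change, among probe sets paired with 1 gene that passed the threshold with both ila1 arrays beyond both ZH11 arrays, taking 1 probe set per gene, plus up to 3 members of each list with the smallest unadjusted p. The rule put genes with a description first. The tables hold no descriptions, so a gene counts as named if it has a symbol or synonym beyond a locus number. For the same reason the 26 lists, planned as words in gene descriptions, were turned into symbol patterns for the same gene families after the gene tables were seen and before any gene value was compared. The lists are cellulose synthases, cellulose synthase-like genes, xylan synthesis, lignin synthesis, laccases, peroxidases, wall loosening, pectin, COBRA-like genes, tubulins, brassinosteroid, auxin, gibberellin, ethylene, jasmonate, WRKY, pathogenesis-related genes, MAP kinases, MADS-box genes, named secondary wall genes, named lamina joint genes, and, as markers of other cell types or RNA quality, photosynthesis, cell division, cuticle, ribosomal proteins and heat stress. Another 10 lists were added at that point as a separate family. Names were assigned by symbol, so a list holds only the named members of its family.

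Each list with at least 5 tested genes (23 of the 26) was tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of the family. None of the 6 list calls held with an estimated correlation, where the smallest unadjusted p was 0.0635 and the smallest adjusted p 0.532. Correlations estimated from 4 arrays are themselves poorly known.

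The fit was tested on simulated data with the means of these arrays. With 200 of 34355 probe sets changed and spreads drawn from the fitted prior, it called 9.6% of changes of 2-fold, 81.2% of 4-fold and 97.6% of 8-fold, and 4.07% of its calls had not been changed. That setting was added after a run with the spreads as estimated per probe set, in which the fit called 70.8% of 2-fold changes and 11.9% of its calls had not been changed, above the nominal rate. Both settings changed a far smaller share of probe sets than the 15.1% called in these data. The Benjamini-Hochberg threshold depends on that share, so these rates hold for the simulated share only. In the same kind of simulation over 15633 genes, camera found each of 50 lists of 40 genes shifted by 0.5 and called 2% of unshifted lists, with genes drawn independently of each other. It used the spreads as estimated per probe set and unadjusted p-values. All genes of a shifted list moved alike and no other gene changed, so these rates hold for that setting only.

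The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter on low values, the lowest 60% left out, the replicate number as a block, each array left out in turn, no trend in the prior, probe sets shared between transcripts left out, the mean of all probe sets of a gene, camera with an estimated correlation and fry. Scaling each array to its 21 probe sets for bacterial hybridization controls was added after seeing the data. ILA1 was to be tested as a check of the labels and is not analysed here, since 0 rows of the gene tables name it.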

Results

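Gene expression was measured in the lamina joint of rice, the hinge between leaf blade and leaf sheath that sets the leaf angle, in plants at the tillering stage. Total RNA was hybridised to the Affymetrix Rice Genome Array, a 1-colour array on which a transcript is read by 1 or more probe sets. The wild type was the japonica cultivar Zhonghua11 (ZH11, 2 arrays), and the other group was ila1 (2 arrays), a mutant with a wider leaf angle whose affected gene encodes a Raf-like kinase of the MAP kinase cascade. The comparison asks which transcripts of the lamina joint differ between mutant and wild type. The labels call the arrays of a genotype biological replicates. Median signal was 56.0 and 57.9 on the ZH11 arrays and 53.6 and 53.6 on the ila1 arrays, and mean signal was 345 and 346 against 302 and 305. Across 57258 probe sets, which are not independent of each other, log2 signals of the ZH11 arrays correlated at 0.995 and those of the ila1 arrays at 0.983, and the 4 pairs across genotypes lay between 0.957 and 0.966. The number of arrays limits the precision of every value given here. The level of ILA1 itself, which would check the labels, is not reported because neither gene table used here pairs a probe set with it. Of 14 tested probe sets for reporter and vector sequences, a group foreign to rice and chosen after values were seen, 6 rose in ila1 by log2 fold changes of 3.88 to 7.58. Their signals lay between 1.22 and 207 on the ZH11 arrays and between 815 and 13980 on the ila1 arrays. They count among the calls given below. Without ZH11 replicate 1, every probe set called higher in ila1 was of this reporter and vector group, so no other rise kept its call there.

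Among genes with a name, the expansin genes EXPB11, EXPA2 and EXPB6, whose products loosen the cell wall, were among the 12 largest rises in ila1, and the lipoxygenase gene CM-LOX1 and the transcription factor genes WRKY76 and WRKY71 were among the 12 largest falls. The beta-expansin EXPB11 rose 8.79-fold, from a signal of 220 ± 22.1 in ZH11 to 2085 ± 473 in ila1 (SD, n = 2 each; log2 fold change 3.14 ± 0.19 SE, limma adjusted p = 0.00298). CYP85A1, the C-6 oxidase of brassinosteroid synthesis, rose 4.21-fold (log2 fold change 2.07 ± 0.19, limma adjusted p = 0.00564). The lipoxygenase CM-LOX1, an enzyme of oxylipin synthesis, was 11.1-fold lower in ila1, at a signal of 65.6 ± 6.88 against 894 ± 88.2 in ZH11 (log2 fold change -3.48 ± 0.14, limma adjusted p = 0.00196). BRXL2, a BREVIS RADIX-like gene, showed the largest fall of a named gene, 20.0-fold, from 1168 ± 228 to 42.7 ± 0.134 (log2 fold change -4.32 ± 0.17, limma adjusted p = 0.0019).

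Of 34355 probe sets tested, 5191 differed between the genotypes at a limma adjusted p under 0.05, 1619 higher and 3572 lower in ila1. A change of at least 2-fold in all 4 pairs of an ila1 and a ZH11 array was found for 1721 probe sets, 256 higher and 1465 lower in ila1. The 2 other ways to split the 4 arrays into pairs gave 1 and 6 such probe sets, and with only 3 splits no permutation p under 0.05 can be had. Both put 1 array of each genotype in each group, which turns the genotype difference into spread, so low counts follow from that. The balance of higher and lower calls moved with the scaling of the arrays. Quantile normalization gave 2928 higher and 2860 lower, median centring 2083 and 3066, and arrays scaled to hybridization controls, an alternative chosen after seeing the data, 4341 higher and 2259 lower. The median log2 fold change of all tested probe sets was -0.07 as deposited, 0.03 after quantile normalization and 0.16 with arrays scaled to the controls. Over the 15633 genes used for the lists it was -0.02 as deposited, 0.13 after quantile normalization, 0.05 after median centring and 0.24 with arrays scaled to the controls. With ZH11 replicate 1 or ZH11 replicate 2 left out the count of calls was 22 or 114, and with ila1 replicate 1 or ila1 replicate 2 left out it was 10539 or 14800, each fit assuming that the lone array varies like the other group. Of the named genes, only BRXL2 and PDC1 kept their call without ZH11 replicate 1, and only these, ACA7, CM-LOX1, BFRP, WRKY71 and HSFA3 kept it without ZH11 replicate 2.

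The 12 named genes with the largest rises were SAUR39, EXPB11, GLN2, EXPA2, CYP85A1, MHX1, MYBAS1, PSY2, EXPB6, CIPK18, GBSS1 and CKX11, at log2 fold changes from 4.58 down to 1.44. SAUR39, a small auxin-up RNA gene, read 16.4 and 26.5 on the ZH11 arrays and 2135 and 351 on the ila1 arrays, so that its rise (log2 fold change 4.58 ± 0.83, limma adjusted p = 0.0289) had the largest SE of the 12. GLN2, a glutamine synthetase, rose on 1 of its 2 tested probe sets, from 14.5 ± 4.75 to 178 ± 105. With a pseudocount of 64 the log2 fold change of GLN2 was 1.55 instead of 2.57 and that of CIPK18, a kinase of calcium signalling, 0.98 instead of 1.49. PSY2, a phytoene synthase of carotenoid synthesis, rose from 75.5 ± 0.354 to 260 ± 21.3, GBSS1, a granule-bound starch synthase, from 78.9 ± 3.42 to 249 ± 25.7 (1 of its 3 other tested probe sets also rose), and CKX11, a cytokinin oxidase, from 67.6 ± 13.8 to 211 ± 39.5. Among genes without a name in the tables, 85 rose by more than CKX11.

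The 12 named genes with the largest falls were BRXL2, NPR3, PDC1, ACA7, CPK21, CM-LOX1, DXPS, BFRP, WRKY76, GRXS3, KIN8B and WRKY71, at log2 fold changes from -4.32 to -3.03. NPR3, a relative of the salicylic acid receptor NPR1, fell from 1686 ± 239 to 98.6 ± 25.9, and its 3 other tested probe sets fell too. The calcium pump ACA7 fell from 2749 ± 273 to 194 ± 21.6 and the calcium-dependent kinase CPK21 from 1010 ± 196 to 69.5 ± 34.9. PDC1, a pyruvate decarboxylase, read 23.4 ± 3.62 in ila1 against 542 ± 132 in ZH11, and GRXS3, a glutaredoxin, 139 ± 19.4 against 1333 ± 159. Among genes without a name, 67 fell by more than WRKY71. All 24 named genes kept their call under each of the 3 other scalings, but 22 of them missed the threshold without ZH11 replicate 1 (all but BRXL2 and PDC1) and 18 without ZH11 replicate 2.

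**Figure D1:**
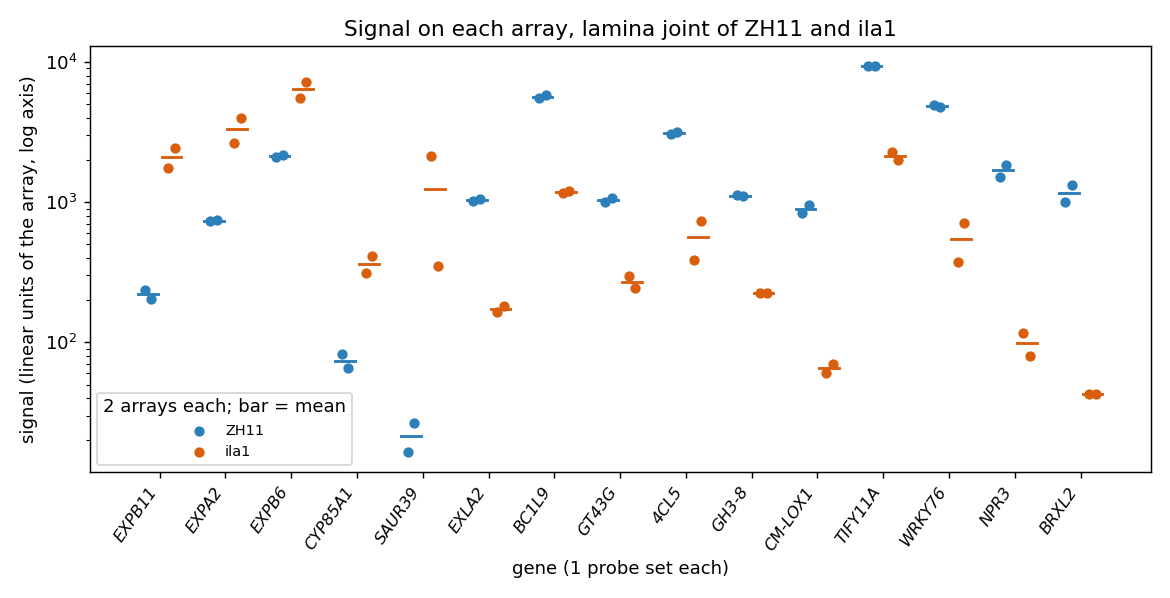
Signal of 15 genes on each array, on a log axis: points are the 2 ZH11 arrays (blue) and the 2 ila1 arrays (orange), bars are group means, and each gene is shown by 1 probe set. Both ila1 arrays lie above both ZH11 arrays for EXPB11, EXPA2, EXPB6, CYP85A1 and SAUR39 and below them for the 10 others.

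Of 35 tested genes of jasmonate synthesis and signalling, 20 fell and 0 rose over all probe sets (21 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.83, or -0.82 relative to all tested genes. The camera adjusted p of limma was 8.71e-07 with the preset correlation, and adjusted p = 0.532 with an estimated correlation. The list median was -0.48 with the mean of all probe sets of a gene and also with no filter on low values. CM-LOX1, LOX5 (log2 fold change -2.76 ± 0.13) and TIFY11A, a JAZ repressor of jasmonate signalling (-2.12 ± 0.10), had the smallest p-values. Of 6 tested WRKY transcription factors 5 fell (5 adjusted over the list alone), at a median of -1.79 (camera adjusted p = 0.00264, but adjusted p = 0.532 with an estimated correlation). WRKY76 fell by 3.19, WRKY24 by 2.35 and WRKY62 by 2.26 on the log2 scale. WRKY71 fell by 3.03 on 1 probe set and by 1.32 on the probe set with the higher signal. Under the 3 other scalings 18 or 19 jasmonate genes and 4 or 5 WRKY genes were lower. Without ZH11 replicate 1 no gene named in this paragraph passed, and without ZH11 replicate 2 only CM-LOX1 and WRKY71 did, while both lists kept their camera calls.

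Of 18 tested ethylene genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone), at a median log2 fold change of -0.61, or -0.60 relative to all tested genes (camera adjusted p = 0.0051, but adjusted p = 0.532 with an estimated correlation). The transcription factors ERF25 (-2.09 ± 0.10), ERF24 (-1.98 ± 0.15) and EREBP1 (-0.80 ± 0.08) had the smallest p-values of the list. With arrays scaled to hybridization controls the list median was -0.35, or -0.59 relative to all tested genes, and EREBP1 read -0.53. With no filter on low values the list median was -0.38. In the MAP kinase list of 17 genes, 4 fell and 1 rose (5 and 2 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.399). MPK7 fell by 2.66, MPK5 by 1.35 and MAPKK1 by 0.87 on the log2 scale. In the list of pathogenesis-related genes, mostly chitinases, 2 of 11 fell (2 adjusted over the list alone; camera adjusted p = 0.215): Cht10 at -0.61 ± 0.13 and Cht7 at -0.51 ± 0.11, both of which missed the threshold under each of the 3 other scalings. Cht6 read -2.23 ± 0.59 and did not pass. It read -1.32 without ila1 replicate 1 and -3.14 without ila1 replicate 2, fits that rest on 1 ila1 array. The list median moved from -0.47 to -0.07 without ila1 replicate 1 and to -0.84 without ila1 replicate 2. Of all alternatives the list passed only in the latter, as lower, with the spread taken from the ZH11 pair. The median absolute log2 difference between the ila1 arrays was 0.574 in this list, against 0.182 in random lists matched on signal. No gene named in this paragraph kept its call without ZH11 replicate 1 or without ZH11 replicate 2.

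Of 19 tested genes of lignin synthesis, 7 fell and 0 rose (12 and 2 adjusted over the list alone), at a median log2 fold change of -0.50, or -0.48 relative to all tested genes (camera adjusted p = 0.0051, but adjusted p = 0.738 with an estimated correlation), and the list missed the threshold with fry. With arrays scaled to hybridization controls 2 were higher and 6 lower, and the list median was -0.23, or -0.47 relative to all tested genes. The 4-coumarate-CoA ligases 4CL5 and 4CL4 fell by 2.51 and 0.78 (4CL4 by 0.51 after quantile normalization) and the cinnamyl alcohol dehydrogenase CAD6 by 1.73 on the log2 scale. Of 10 genes for xylan synthesis, 4 fell and 0 rose (5 and 0 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0695) at a median of -0.31. It passed as lower without ila1 replicate 1 (median -0.57), with fry and with arrays scaled to hybridization controls (median -0.04, or -0.28 relative to all tested genes). The glycosyltransferases GT43G (-1.89 ± 0.15) and GT43H (-1.08 ± 0.13) fell, as did GT43C (-0.80 ± 0.14), which missed the threshold with arrays scaled to hybridization controls, where 2 xylan genes were lower. Of 15 cellulose synthase-like genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.36): CSLF6, which makes mixed-linkage glucan, at -1.73 ± 0.32, CSLC7 at -1.45 ± 0.10 and CSLD2 at -1.37 ± 0.20. The calls of these genes were lost without ZH11 replicate 1 and without ZH11 replicate 2, where the lignin list kept its camera call.

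None of the 9 cellulose synthases passed the limma test (0 adjusted over the list alone; 1 at an unadjusted p under 0.05; camera adjusted p = 0.519). The list had a median of -0.11 and passed as lower without ila1 replicate 1 only (median -0.22). Without ila1 replicate 2 it turned to higher (median 0.10) and did not pass. The nearest was CESA6 at -1.43 ± 0.33 (unadjusted p = 0.0077, limma adjusted p = 0.0505), which passed with a pseudocount of 64 and with no filter on low values, and CESA4 and CESA9, which serve the secondary wall, read -0.21 ± 0.12 and 0.20 ± 0.18. With arrays scaled to hybridization controls CESA4 read 0.06 and CESA9 0.44, neither passing. In a list of 7 named secondary wall genes 2 fell, GT43C and IRX14 (-0.69 ± 0.12), of which IRX14 missed the threshold after quantile normalization and both did with arrays scaled to hybridization controls, with 3 adjusted over the list alone and a camera adjusted p of 0.36. The COBRA-like genes BC1L6 and BC1L9 fell by 2.78 ± 0.58 and 2.24 ± 0.09 on the log2 scale. BC1L6 read -3.67 without ila1 replicate 1 and -1.89 without ila1 replicate 2. BC1, the COBRA-like gene behind a brittle culm mutant, read 0.26 ± 0.15 (2 of 3 lower adjusted over the list alone), 0.39 without ZH11 replicate 1, 0.12 without ZH11 replicate 2 and 0.51 with arrays scaled to hybridization controls, passing in none. These 3 genes were too few for a list test, as were the 2 peroxidases PRX112 (-0.56 ± 0.15) and PRX74 (-0.64 ± 0.17), which passed only adjusted over the list alone, and the pectin acetylesterase PAE1 (0.19 ± 0.10; 0 adjusted over the list alone), which passed as higher after quantile normalization and with arrays scaled to hybridization controls. Of 7 laccases 1 fell (1 adjusted over the list alone; camera adjusted p = 0.506), LAC15 at -1.41 ± 0.31, a call that ended under median centring, with a pseudocount of 64 and with arrays scaled to hybridization controls. LAC19 at -1.63 ± 0.52 and LAC24 at -0.58 ± 0.31 did not pass, and the median absolute log2 difference of the laccases was 0.818 between the ila1 arrays and 0.471 between the ZH11 arrays, against 0.219 and 0.117 in random lists. No call of this paragraph held without ZH11 replicate 1 or without ZH11 replicate 2. CESA6 read -1.92 without ila1 replicate 1 and -0.94 without ila1 replicate 2, LAC19 -0.87 and -2.38, and PRX112 -0.42 and -0.69. In the same order, PRX74 read -0.40 and -0.88, LAC24 -0.18 and -0.99, CESA9 -0.02 and 0.41, and PAE1 0.25 and 0.13. Fits with 1 ila1 array take their spread from the ZH11 pair, so only sizes are given for these genes.

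Wall loosening genes moved in both directions. Of 20 tested expansin and xyloglucan endotransglucosylase genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone), and the list had a median of 0.04 (camera adjusted p = 0.586). With 1 array left out the median was 0.01 without ZH11 replicate 1, 0.06 without ZH11 replicate 2, 0.13 without ila1 replicate 1 and -0.04 without ila1 replicate 2, and the list passed in none of these fits. Quantile normalization gave 5 higher and 3 lower, and there, with fry and with arrays scaled to hybridization controls the list's direction turned to lower without passing. EXPA2 rose from 739 ± 6.10 to 3331 ± 958 and EXPB6 from 2136 ± 52.2 to 6372 ± 1226. The expansin-like EXLA2 fell by 2.48 ± 0.12 on the log2 scale (limma adjusted p = 0.00234). None of 11 tubulin genes passed the limma test (0 adjusted over the list alone; 1 at an unadjusted p under 0.05; camera adjusted p = 0.36), with TubA at -0.19 ± 0.07, TUBG2 at 0.30 ± 0.12 and TUBB7 at -0.86 ± 0.34. The tubulins differed between the ila1 arrays by a median absolute log2 value of 0.6002, against 0.1800 in random lists. TubA and TUBB7 read -0.18 and -1.36 without ila1 replicate 1, and -0.19 and -0.36 without ila1 replicate 2. These fits rest on 1 ila1 array and take their spread from the ZH11 pair, so only sizes are given for single genes. Without ila1 replicate 2 TUBG2 read 0.35 and the tubulin list had a median of 0.35 (from 0.33). Of all alternatives the tubulin list passed only in that fit, as higher. Without ila1 replicate 1 the list median was 0.10. With arrays scaled to hybridization controls TubA read 0.09. The calls of the wall loosening genes named here were lost without ZH11 replicate 1 and without ZH11 replicate 2. Their log2 fold changes without ZH11 replicate 1 (EXPB11 3.23, EXPA2 2.11, EXPB6 1.53, EXLA2 -2.50) and without ZH11 replicate 2 (3.04, 2.13, 1.58 and -2.45) stayed close to the values from all 4 arrays.

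**Figure D2:**
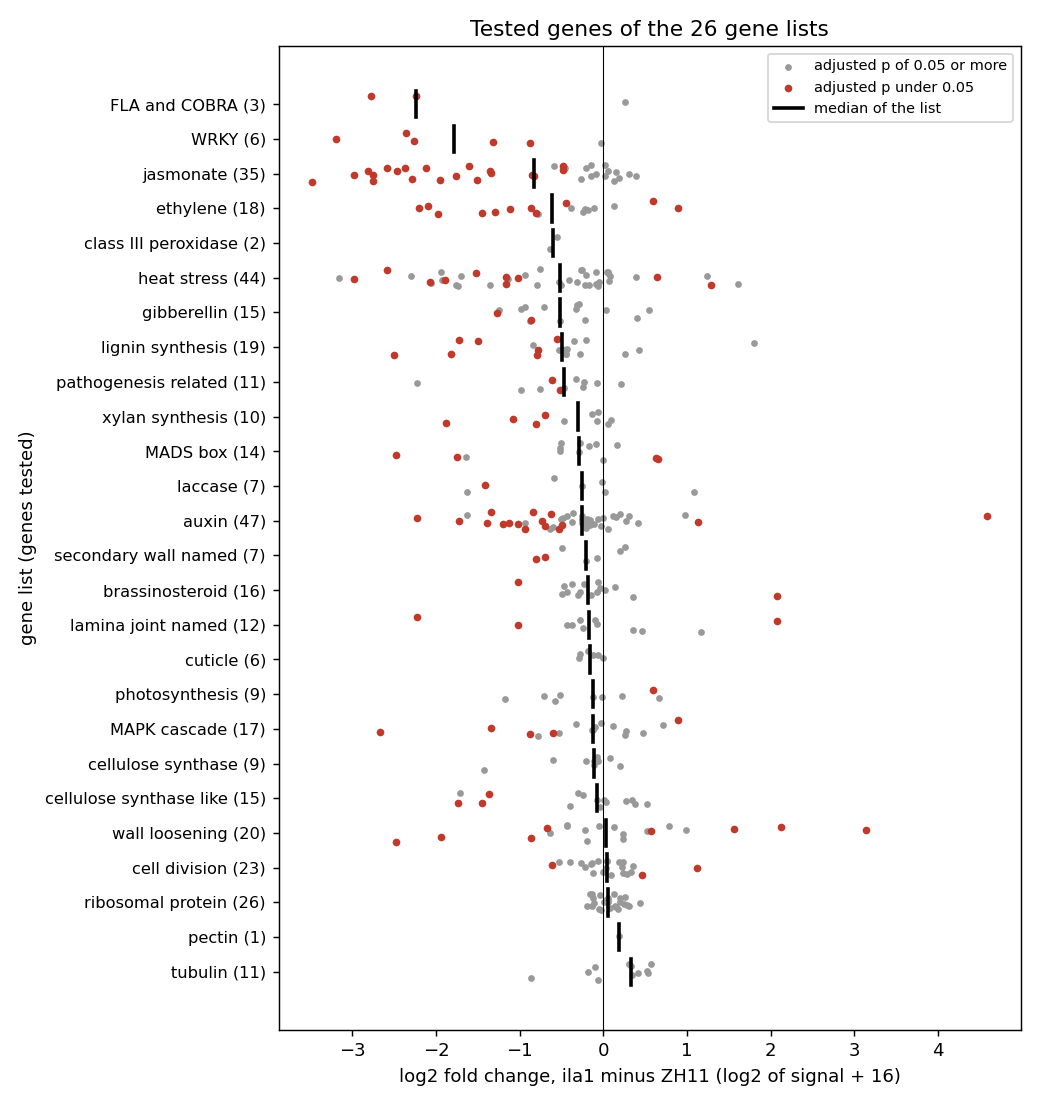
Log2 fold change (ila1 minus ZH11, on log2 of signal plus 16) of each tested gene of the 26 lists, with the number of tested genes in brackets: red points passed a limma adjusted p of 0.05 over all probe sets, grey points did not, and black bars are list medians. The WRKY and jasmonate lists have medians of -1.79 and -0.83, and the ribosomal protein list has no red point, although 4 of its genes were called higher after quantile normalization.

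Of the brassinosteroid, auxin and gibberellin lists, tied to leaf angle, only auxin passed camera with all 4 arrays as deposited and the preset correlation. Over all tested probe sets 15.1% were called, and no test set the counts of these lists against that share. Of 16 brassinosteroid genes 1 rose and 1 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.36): CYP85A1 rose and BZR1, a transcription factor of the pathway, fell by 1.02 ± 0.12 on the log2 scale. BZR2 read -0.44 ± 0.11 and passed adjusted over the list alone. It read -0.51 without ila1 replicate 1, -0.36 without ila1 replicate 2 and -0.17 after quantile normalization, where it did not pass. Fits without an ila1 replicate rest on 1 ila1 array, so only sizes are given for single genes there. Of 12 genes named for lamina joint development 1 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.71), namely CYP85A1, BZR1 and the auxin-conjugating enzyme gene GH3-8, which fell by 2.23 ± 0.11. Of the lamina joint genes 4 were higher and 2 lower with arrays scaled to hybridization controls, and of the brassinosteroid genes 2 and 1. Of 47 auxin genes 14 fell and 2 rose (17 and 3 adjusted over the list alone), at a median of -0.25, or -0.24 relative to all tested genes (camera adjusted p = 0.00657, but adjusted p = 0.738 with an estimated correlation). With arrays scaled to hybridization controls 8 fell and 3 rose, at a median of -0.01, or -0.25 relative to all tested genes. The median was -0.15 after quantile normalization and -0.47 without ila1 replicate 2, and the list kept its camera call in all 3 fits. IAA19 fell by 1.39 and the auxin response factor ARF15 by 1.13 on the log2 scale. Of 15 gibberellin genes 2 fell (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0838), at a median of -0.52. These were the DELLA-like SLRL1 at -1.27 ± 0.16 and the semidwarf gene GA20OX2 at -0.87 ± 0.13, while CPS1 at -1.25 ± 0.29 did not pass over all probe sets. CPS1 passed with a pseudocount of 64 and with no filter on low values. It read -0.86 without ila1 replicate 1 and -1.65 without ila1 replicate 2. The gibberellin list passed as lower after quantile normalization (median -0.45), with arrays scaled to hybridization controls (-0.31), with fry, without ZH11 replicate 2 (-0.67) and without ila1 replicate 2 (-0.43). Each single-gene call made here with all 4 arrays was lost without ZH11 replicate 1 and without ZH11 replicate 2.

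Of 14 MADS-box genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.36). MADS15, a gene of the APETALA1 clade, fell by 2.47 ± 0.25, MADS2 rose by 0.62 ± 0.10 and MADS50, a flowering activator, rose by 0.66 ± 0.12 on the log2 scale. With a pseudocount of 64 MADS2 rose by 0.37. Without ila1 replicate 2 the list passed as lower (median -0.32, from -0.29). In the heat and dehydration list of 44 genes, 8 fell and 2 rose (8 and 3 adjusted over the list alone), at a median of -0.52, or -0.50 relative to all tested genes (camera adjusted p = 0.0315, but adjusted p = 0.762 with an estimated correlation). The smallest p-values were those of heat stress transcription factors, HSFA3 at -2.59 ± 0.10, HSFA9 at -1.89 ± 0.15 and HSFB1 at -1.52 ± 0.13. Genes of the list differed between the ZH11 arrays by a median absolute log2 value of 0.242, against 0.0891 in random lists matched on signal, and between the ila1 arrays by 0.296, against 0.2005. Without ZH11 replicate 1 or without ila1 replicate 1 the list no longer passed (camera adjusted p = 0.176 and 0.181, in a range over all alternatives from 1.69e-06 to 0.762), at medians of -0.20 and -0.36, and it missed the threshold with fry too. Under scaling to hybridization controls 4 were higher and 7 lower, and the median was -0.28, or -0.52 relative to all tested genes. Of the genes named here only HSFA3 kept its call without ZH11 replicate 2 and none did without ZH11 replicate 1.

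Markers of other cell types and signs of RNA quality were set beside these changes. Of 9 photosynthesis genes 1 rose, PSB28 at 0.59 ± 0.13 (0 adjusted over the list alone, camera adjusted p = 0.986). PSAH at -0.71 ± 0.23 and OEE3 at -0.52 ± 0.22 did not pass. They read -0.40 and -0.19 without ila1 replicate 1, and -1.01 and -0.85 without ila1 replicate 2, fits that rest on 1 ila1 array. The list had a median absolute log2 difference of 0.657 between the ila1 arrays, against 0.162 in random lists. The list's median had a negative sign (-0.13) where camera gave a positive direction, and the median was 0.06 after quantile normalization. It was 0.24 without ila1 replicate 1, -0.50 without ila1 replicate 2, -0.18 without ZH11 replicate 1 and -0.08 without ZH11 replicate 2. The list passed in none of these fits. Camera's direction turned to lower without ila1 replicate 2, without ZH11 replicate 1 and under each of the 3 other scalings. It also did with no filter on low values, with the replicate number as a block and with the mean of all probe sets of a gene. Of 23 cell division genes 2 rose and 1 fell (0 adjusted over the list alone; camera adjusted p = 0.519): CYCA1-4 at 1.12 ± 0.19, MCM2 at 0.46 ± 0.10 and KIN7C at -0.61 ± 0.14, the last not passing under any of the 3 other scalings. PSB28, MCM2 and KIN7C also missed the threshold with no filter on low values, and no call of this paragraph held without ZH11 replicate 1 or without ZH11 replicate 2. None of 6 cuticle genes passed the limma test (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; camera adjusted p = 0.506), with LTP110-A at -0.29 ± 0.12. None of 26 ribosomal protein genes passed the limma test (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.215). RPL5A read 0.28 ± 0.08 (0.25 without ila1 replicate 1 and 0.31 without ila1 replicate 2). After quantile normalization 4 were called higher and the list passed camera as higher (median 0.26, from 0.06), and with arrays scaled to hybridization controls 6 were and the list passed too (median 0.33). It also passed with fry. The ratio of 3' to 5' actin signal, a sign of RNA integrity, was 6.94 and 7.98 in ZH11 and 7.06 and 8.20 in ila1, and that of GAPDH 2.28 and 2.57 against 2.55 and 2.26. The control probe set for 28S rRNA read 2523 and 2317 in ZH11 against 1409 and 1825 in ila1, and that for 25S rRNA 908 and 1047 against 578 and 784. That for 18S rRNA, at 2128 and 1548 against 1745 and 2528, did not separate the genotypes. All 21 probe sets for the bacterial hybridization controls read lower on both ila1 arrays than on both ZH11 arrays, by 0.27 ± 0.07 on the log2 scale (SD over probe sets). The 36 probe sets for poly-A spike controls were each lower in ila1, by 0.30 ± 0.11, 27 of them on both ila1 arrays. The 6 for the hybridization control cre were lower by 0.04 ± 0.03, 2 of them on both ila1 arrays. The cre probe sets read near the top of the intensity scale and were left out of the scaling to hybridization controls.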

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

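The 5191 calls, the 1721 probe sets at least 2-fold apart and the 6 list calls stayed within 1.5 times their counts under the scalings (1 of them, to hybridization controls, added after seeing the data), pseudocounts and filters. Which probe sets were called, and their balance of higher and lower, changed more. Of the 5191 calls, 4479 stayed after quantile normalization, 4685 after median centring and 3877 with arrays scaled to hybridization controls. Leaving out 1 array moved the calls to between 22 and 14800 and the 2-fold count to between 2000 and 2989. Fewer array pairs then had to be 2-fold apart, so the 2-fold count could only stay or rise. Without a ZH11 array the spread rests on the ila1 pair, which lay 0.18 apart in median absolute log2 signal, and without an ila1 array on the ZH11 pair, which lay 0.10 apart. All 5191 calls had both ila1 arrays beyond both ZH11 arrays, so that leaving out 1 array could not turn the sign of any of them. The 2 other splits of the arrays gave 1 and 6 probe sets at least 2-fold apart, and limma called 0 in each (140 and 65 at an unadjusted p under 0.05). Both splits put 1 array of each genotype in each group, so the genotype difference counts as spread there. Low counts follow from that and do not measure false calls. Shifted lists numbered 5 to 10 with 1 array left out, 0 with an estimated correlation and 13 with fry, which asks if a list moves one way and does not compare it with other genes. Of the lists without a call, the direction turned for the cellulose synthase and lamina joint lists without ila1 replicate 2, the cuticle list without ila1 replicate 1, the wall loosening list after quantile normalization, with fry and with arrays scaled to hybridization controls, and the photosynthesis list in 8 of its 15 alternatives. The cause of the move to 10 lists without ila1 replicate 2 was not tested. Under fry the lignin and heat lists missed the threshold, and 9 further lists passed: xylan synthesis, cellulose synthase-like, brassinosteroid, gibberellin, MAP kinases, secondary wall and lamina joint genes as lower, and cell division and ribosomal proteins as higher.

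Of the genes named from the lists, PRR1 turned from -0.29 to 0.28 without ila1 replicate 2, and read -0.86 without ila1 replicate 1 (the cause was not tested). Without ila1 replicate 1 CESA9 turned from 0.20 to -0.02 and LTP from -0.13 to 0.07, without a call. Of other calls and non-calls of genes named from the lists, apart from arrays left out, 34 calls were lost, 18 were gained, 7 comparisons changed sign without a call and 792 kept their side. The 7 were LTP (0.05) and LTPL1 (0.06) after quantile normalization and, with arrays scaled to hybridization controls, LTP (0.14), LTPL1 (0.09), CESA4 (0.06), TubA (0.09) and PRR73 (0.01). Apart from arrays left out, the 24 leading genes kept direction and call in each of the 214 comparisons that could be made. The replicate block gave 4816 calls, of which 4292 were among the 5191, 1721 2-fold probe sets and 6 lists. With it Cht10, Cht7, KIN7C, MCM2, PSB28, NRAMP3, YSL13 and MADS50 missed the threshold and CESA6, CPS1 and Cht6 passed. Deviations of same-numbered arrays correlated at 0.103, and with 2 pairs the numbers are not shown to pair the samples. ILA1 has no value under any setting because the gene tables do not name it. Low signals limit what can be seen, since 22903 probe sets were too dim to be tested.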

Other observations

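Single transport and storage genes outside the fixed lists also differed, in lists added after the gene tables were seen and before any gene value was compared. Of all tested probe sets 15.1% were called, and no test set the counts of the lists against that share. None of these 10 lists passed camera (smallest adjusted p = 0.158, for xylan acetylation and diterpenoid phytoalexins). With fry 1 of them passed, xylan acetylation (fry adjusted p = 0.0156). Of 20 potassium transporters 5 fell and 1 rose, with the smallest p-values for HAK7 at -1.60 ± 0.12, HAK5 at -0.50 ± 0.07 and HAK3 at -1.30 ± 0.19; HAK5 missed the threshold with arrays scaled to hybridization controls, where 3 potassium transporters rose and 2 fell. Of 11 phosphate genes 2 rose and 2 fell: the SPX-domain gene SPX2 at 1.39 ± 0.14 rose, and the transporters PHT1-1 at -1.23 ± 0.10 and PHT1-8 at -1.09 ± 0.19 fell. In the sugar transport and invertase list 3 of 23 genes fell, among them the sucrose transporter SUT4 at -1.79 ± 0.18. Of 7 xylan O-acetyltransferase genes 2 fell, XOAT2 at -1.69 ± 0.28 and XOAT6 at -0.88 ± 0.12. Of 7 starch genes 2 rose, GBSS1 at 1.48 ± 0.13 and SSII-1 at 0.67 ± 0.14. Of 20 aquaporins 1 rose, TIP2-2 at 0.55 ± 0.11 (a call lost with no trend in the prior), and 1 fell, the silicon channel gene NIP2-1 at -1.26 ± 0.17. Of 28 metal transport genes 1 rose and 2 fell, among them YSL16 at -1.31 ± 0.17. Of 7 metallothioneins MT-2 rose (0.71 ± 0.09) and OsMT2b fell (-0.63 ± 0.07, and -0.36 with arrays scaled to hybridization controls). The 13 diterpenoid phytoalexin genes and 7 clock genes held 0 limma calls (4 and 1 at an unadjusted p under 0.05). No gene named in this paragraph kept its call without ZH11 replicate 1 or without ZH11 replicate 2.

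Of the tests in the following paragraphs, the list medians set against all tested genes, the jasmonate median per ila1 array, the shares of lower probe sets, the scaling to hybridization controls and the differences between arrays of 1 genotype were chosen after the results had been seen. The fits with quantile normalization, median centring and an estimated correlation were planned. The jasmonate, WRKY and ethylene lists were lower in ila1 by camera with the preset correlation, but each had an adjusted p = 0.532 with an estimated correlation. A scaling difference between arrays argues poorly for this, because after quantile normalization, which moves genes by different amounts, the median of each of the 3 lists lay below that of all tested genes, the nearest by 0.59 (a difference of -0.59), and each list kept its camera call with the preset correlation. Time of day at sampling stays open, as clock genes of the ila1 arrays lay a median 0.635 from ZH11 on the log2 scale, and the jasmonate median was below ZH11 on both ila1 arrays (-0.90 and -0.75), which a rhythm with more than 1 phase could give. The criterion first used the nearer ila1 array (0.48) and was changed to both arrays after its outcome was seen. Under the first (a difference under 0.5) time of day would have been labelled as excluded. That criterion left out the other ila1 array (0.92), so it could not exclude time of day. Wounding at harvest and the mutation itself also stay open, as untested.

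More probe sets were called lower than higher in ila1. After quantile normalization the share of lower calls was 49.4%, and after median centring 59.5%, from 68.8% as deposited. Quantile normalization gives all arrays the same distribution, which draws the balance toward even whatever its cause. Its share therefore cannot say whether scaling accounts for the balance of calls. Of the probe sets at least 2-fold apart in all 4 array pairs, 85.1% were lower as deposited and 78.0% after quantile normalization, so that most stayed lower there. Scaling to the hybridization controls gave 34.2% and 65.9%, but it moves all genes of an array alike, so that the size of the shift sets these shares and they weigh neither way. Whether the ila1 samples held less RNA per array or a different composition of RNA was not tested.

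The ila1 arrays differed from each other in clock genes, which were singled out after their values were seen. Log2 signals of CCA1, a morning gene, were 6.40 and 9.43 on ila1 replicates 1 and 2 and 8.60 and 8.68 in ZH11, and those of PCL1, an evening gene, were 12.33 and 6.53 against 9.66 and 8.84. The clock list's median absolute log2 difference between the ila1 arrays was 1.14, against 0.175 in random lists of the same size and signal. The aquaporin (0.618 against 0.193), photosynthesis (0.657 against 0.162) and diterpenoid phytoalexin (0.702 against 0.216) lists also differed more than their random lists. Between the ZH11 arrays the difference was 0.0801 in the clock list (0.0680 in random lists) and 0.0790 in the photosynthesis list (0.0562), but 0.211 in the aquaporin list (0.0757) and 0.634 in the diterpenoid list (0.108), so that these 2 differed within both genotypes. Sampling time, light, growth conditions and noise of 1 array stay open, since no label gives a sampling time and the genes were picked because they differ.

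Between the ZH11 arrays the median absolute log2 difference of the heat and dehydration list was 0.242, against 0.0891 in random lists matched on signal, and between the ila1 arrays it was 0.296, against 0.2005. The small heat shock protein gene HSP18.1, singled out after its values were seen, read 12.13 and 6.18 on ZH11 replicates 1 and 2 and 7.53 and 7.26 on the ila1 arrays.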
